A study of Rattus norvegicus with 89 samples.

How the data were processed

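Kidney RNA of 89 rats was measured on 1-colour Affymetrix rat arrays, 1 array per rat, in 15 groups: saline, gentamicin, tobramycin, cisplatin, cadmium, doxorubicin and valproic acid at day 1 and day 5, and naive rats. The authors deposited a MAS5 signal per probe set as a linear intensity, with 31099 probe sets per array. The MAS5 version, its scaling and the detection calls are not given in the sources used here. Doses and the times of sampling are not given there either. The animal codes mark each rat, and no paired analysis was possible because each rat gave 1 array and the codes link no rat to another.

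Groups were taken from the sample titles. For 5 arrays (1F104, 1M2, 1M4, 2F114 and 5F137) the treatment text is absent or differs from the title. The text is absent for 1F104 and 1M4, names 5 days of saline for 1M2, and says untreated for 2F114 and 5F137. Rat 1F104 was kept in saline at day 1, as its title says, although its animal number lies next to 2 females of day 5. The sex labels were checked with 2 measured Y-linked genes, whose mean log2 value was at least 7.23 in males and at most 6.26 in females, and 0 arrays contradicted their label. The choices of test, filter, gene lists and alternatives were made before the data were examined, except where said otherwise.

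The 2% trimmed mean of the deposited intensity ran from 91.5 to 352 between arrays, a ratio of 3.84. A rule set in advance scaled the arrays where this ratio exceeds 1.2, so each array was multiplied to a common trimmed mean of 181. Values were then written as log2(signal + 16). The 57 control probe sets were left out, and so were 436 probe sets with several gene symbols and 9780 with none listed. Each of 14218 named genes was represented by the 1 of its probe sets with the highest mean log2 value. Genes were tested if at least 5 arrays exceeded the 40th percentile of all values (a signal of 33.2), which left 11415. Means and SD of a gene are given as scaled signal, and changes as differences of the log2 values. Where every array of the dimmer group lay under 33.2, a fold is given as at least the ratio of the brighter group (from its mean log2 signal) to that limit. Gene positions are those of the GRCr8 assembly. The signal of an array carries no count, so precision is limited by the number of arrays.

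Differences were tested with limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3 with version 1.17.8 of the data.table package, and adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the limit. Sex was a further term. Each treatment was compared with saline of the same day on the arrays of both groups. The fit on all 89 arrays, which pools the spread of all groups, was set in advance as another way of testing. Further contrasts were saline against naive rats, the effect at day 5 minus that at day 1, the mean of 5 nephrotoxicants against valproic acid, gentamicin against tobramycin, males against females among the 18 control rats, and the effect in males minus that in females. In all there were 37 contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

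Of 28 gene lists, 27 with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, over 12 treatment comparisons (324 tests adjusted together), and again with the correlation estimated per list. The list of adrenal cortex genes was too small on these arrays and was not tested. The lists cover tubular injury markers, p53 targets, metal response, Nrf2 targets, heat shock response, ER stress and integrated stress response, cholesterol biosynthesis, fatty acid oxidation and PPAR targets, oxidative phosphorylation, proximal tubule transporters and enzymes, loop of Henle and distal tubule, collecting duct, podocytes, endothelium, macrophages and granulocytes, lymphocytes, fibroblasts and extracellular matrix, cell cycle, inflammatory cytokines and adhesion, interferon response, immediate early genes, lysosome, circadian clock, glucocorticoid response, red blood cells and adipocytes. Lists for saline against naive rats and for males against females were tested in the same way, each family adjusted on its own, a step added after the data were seen. The score of a list in a rat is the mean over its genes of the log2 value minus the mean of control rats of the same sex.

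Genes are named by a rule. In a treatment comparison these are, among genes that pass and whose change has the same sign in every treated rat, the 8 largest rises and the 6 largest falls, and for each list called, the 3 members that pass with the smallest adjusted p. In other contrasts the 5 largest on either side are named. Havcr1, Lcn2, Clu, Cdkn1a, Hmox1 and Mt2A are named in each treatment comparison. Examples of lists that did not pass on the groups compared, and genes of the fit on all arrays, were chosen after their values were seen. The change in a single rat is its log2 value minus the mean of saline rats of its sex and day.

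The other settings chosen in advance were pseudocounts of 1 and 64, no filter on low signal, quantile normalization, the fit on all arrays, array quality weights, all probe sets, rat 1F104 left out or counted at day 5, the 5 arrays with absent or differing treatment text left out, naive rats as control, an estimated correlation for the lists, and leaving out each rat in turn. Chosen after seeing the data were leaving out 4 arrays with a log2 GAPDH 3' to 5' ratio over 1, that ratio as a covariate, and a pooled control of the 18 saline and naive rats. The procedure was tested on simulated data, in which 200 of 11415 genes were moved in each comparison. Changes of log2 0.5 were recovered in 26.9% to 79.1% of cases, of log2 1 in 82.1% to 98.5% and of log2 2 in 97.0% to 100.0%, while 112 of 2055 calls were false. The list that was moved was called in 12 of 12 comparisons. The simulated noise was drawn independently for each gene, so genes of a list were not correlated. The simulation therefore cannot judge the preset correlation of the list tests. Each simulated comparison also had 143 to 194 calls, against at most 13 in a real treatment comparison, and more calls make the adjusted limit easier to pass. The shares recovered are thus not the power of the real comparisons. With cisplatin at day 5, for example, Havcr1 had a log2 change of 3.01 that did not pass.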

Results

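The series holds kidney RNA profiles of 89 Sprague-Dawley rats on Affymetrix arrays, 1 array per rat. The rats received saline, gentamicin (spelled Gentamycin in the labels), tobramycin, cisplatin, cadmium, doxorubicin or valproic acid daily for 1 or 5 days, and a further 6 rats were untreated (naive). The design text counts 5 nephrotoxicants and 2 controls, and the controls are read here from the names as saline and valproic acid. Doses are not in the labels. Of the 15 groups, saline at day 1 has 7 rats, saline at day 5 and doxorubicin at day 5 have 5 each, and the others have 6, with 44 males and 45 females in all. Each array gives a signal for 31099 probe sets, and 11415 named genes were tested. Before scaling, the trimmed mean signal of an array lay between 91.5 and 352. The rank correlation between arrays was 0.898 to 0.988. The number of arrays per group limits the precision of every value below. The question of each treatment comparison is which kidney genes a compound moved from the saline animals of the same day.

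**Figure D1:**
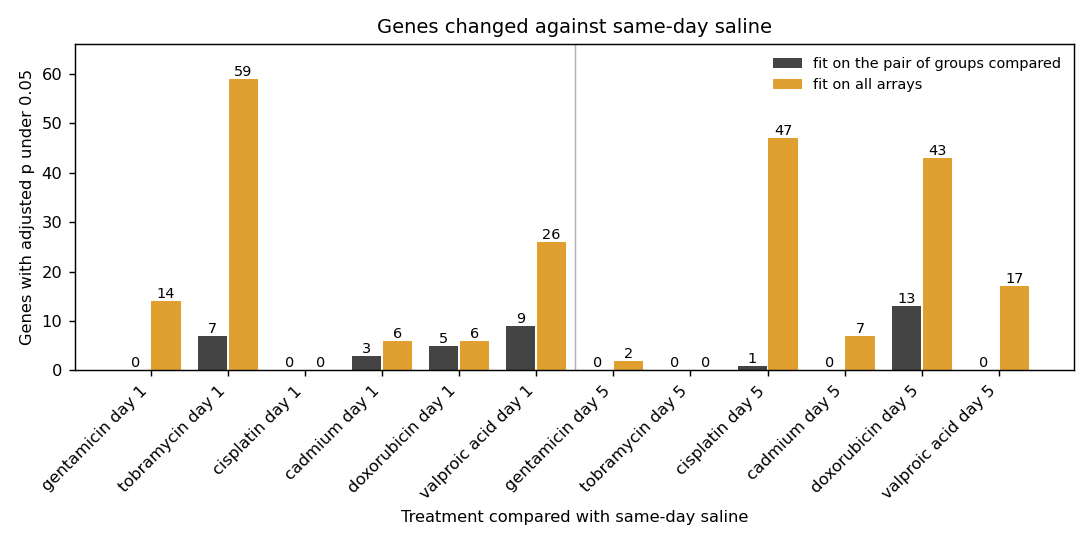
Number of genes passing limma (adjusted p under 0.05) in each of the 12 comparisons of a compound with same-day saline, fitted on the pair of groups compared (dark bars) and on all 89 arrays (orange bars). The dark bars reach 13 for doxorubicin at day 5, and the orange bars reach 59 for tobramycin at day 1.

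Gentamicin and tobramycin are aminoglycoside antibiotics that collect in proximal tubule cells. After 1 day of either compound, genes of the interferon response stood higher than in saline. With gentamicin, 14 of 14 measured interferon genes were higher, with a median log2 change of 1.13 (camera, adjusted p = 6.40e-27, and adjusted p = 0.177 with an estimated correlation). With tobramycin, 14 of 14 were higher with a median of 1.22 (adjusted p = 8.01e-26, and adjusted p = 0.177 with an estimated correlation). Isg15, which encodes a ubiquitin-like antiviral protein (chromosome 5, 172066369 to 172067656 on the GRCr8 assembly), had a mean signal of 615 ± 598 (SD, n = 6) with gentamicin and 641 ± 688 (SD, n = 6) with tobramycin, against 100.02 ± 38.3 (SD, n = 7) in saline. Its log2 change was 2.05 (SE 0.49, adjusted p = 0.535, higher in 6 of 6 rats) with gentamicin and 2.06 (SE 0.44, adjusted p = 0.102, 6 of 6) with tobramycin, so it did not pass in either comparison. The change in single gentamicin rats ran from 0.13 to 3.73. The control groups also differed in these genes: the mean of the list relative to all controls of the same sex was -0.16 ± 0.21 (SD, n = 7) in saline rats of day 1 and 0.17 ± 0.10 (SD, n = 6) in naive rats.

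Tobramycin at day 1 moved 7 genes (5 up, 2 down). Interferon-related genes among them were Ifi44l, which rose 1.92-fold (log2 0.94, SE 0.15, adjusted p = 0.0431), and Irgm, an interferon-induced GTPase, which rose 1.80-fold (log2 0.85, SE 0.14, adjusted p = 0.0431). Slamf9, a receptor of myeloid cells, rose 2.06-fold and LOC100910973 rose 1.69-fold (adjusted p = 0.0431 for each). The clock output gene Dbp rose 2.25-fold, from 148.2 ± 44.6 (SD, n = 7) to 354 ± 92.2 (SD, n = 6), and the clock activator Bmal1 fell by 0.66 on the log2 scale (both with adjusted p = 0.0431). Rnf125, a ubiquitin ligase, fell by 0.70 on the log2 scale (adjusted p = 0.0482). Each of the 7 changes had the same sign in 6 of 6 rats. The count of 7 went to 0 when 1F102, 1F103, 1F104, 1M2, 1M3, 4F128, 4F129, 4F130, 4M29 or 4M30 was left out, to 1 without 1F101, to 20 without 1M1 and to 71 without 4M28. It also went to 0 with a pseudocount of 64, quantile normalization, all probe sets, 1F104 left out or counted at day 5, or without the 5 arrays of absent or differing treatment text. With gentamicin at day 1, 0 genes passed in limma (526 at an unadjusted p under 0.05, where chance gives 571), and 16 passed without rat 2M12.

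Fitting all 89 arrays together gave gentamicin at day 1 14 rises and 0 falls, and tobramycin 45 rises and 14 falls. Of the interferon list, 6 of 14 genes rose with gentamicin and 9 of 14 with tobramycin in that fit. In it, Isg15 rose 4.08-fold with gentamicin (adjusted p = 0.00713) and 4.05-fold with tobramycin (adjusted p = 0.00485). The antiviral GTPase Mx2 rose 3.71-fold (adjusted p = 0.00713) and 3.63-fold (adjusted p = 0.00485). With tobramycin the immunoproteasome subunits Psmb9 and Psmb8 rose 2.02-fold and 1.81-fold (adjusted p = 0.00517 and 0.0420), and the stress chaperone gene Hspa1a fell by 0.58 on the log2 scale (adjusted p = 0.0261). These examples of the fit on all arrays were chosen after their values were seen.

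Other gene lists also shifted at day 1. With gentamicin, 16 of 19 genes of ER stress and the integrated stress response were higher (median 0.14, adjusted p = 4.50e-07, 0.177 with an estimated correlation, and not called against naive rats), as were 11 of 13 inflammatory cytokine genes (median 0.21, adjusted p = 1.85e-05, and 0.182 with an estimated correlation). Tubular injury markers had a median of 0.047 and a mean of 0.21, with 13 of 22 higher (adjusted p = 0.00300, and 0.305 with an estimated correlation). With tobramycin, 15 of 15 markers of macrophages and granulocytes were higher (median 0.27, adjusted p = 2.37e-10, and 0.177 with an estimated correlation), and 1 of 12 heat shock genes was higher (median -0.17, adjusted p = 0.00154, and 0.300 with an estimated correlation). The injury marker Havcr1 (KIM-1) had a log2 change of 0.61 with gentamicin and 1.10 with tobramycin, and did not pass (adjusted p = 0.997 and 0.433). Lymphocyte markers were higher in 7 of 7 cases with each compound (medians 0.16 with gentamicin and 0.31 with tobramycin, adjusted p = 0.0152 and 0.000194, and 0.375 and 0.244 with an estimated correlation). The gentamicin call was kept in 7 of 12 other settings and 10 of 13 fits without a rat. With gentamicin, log2 changes that did not pass were 0.34 for Lcn2, 0.31 for Clu, 0.080 for Cdkn1a, -0.83 for Hmox1 and 0.0062 for the metallothionein Mt2A. With tobramycin they were 0.69 for Lcn2, 0.50 for Clu, 0.25 for Cdkn1a, -0.93 for Hmox1 and 0.060 for Mt2A.

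**Figure D2:**
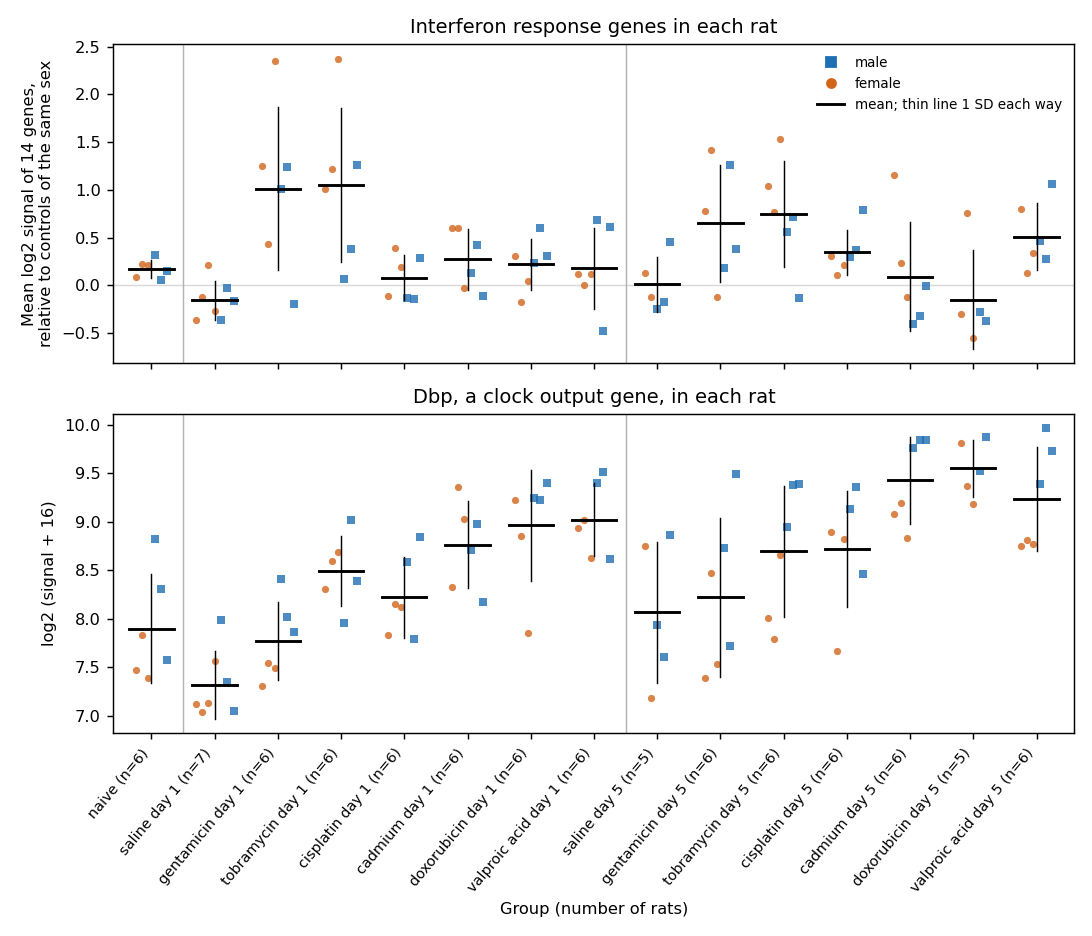
Upper panel, mean log2 signal of 14 interferon genes relative to control rats of the same sex. Lower panel, log2 signal of Dbp. Each point is 1 rat (squares male, circles female), the bar is the group mean and the thin line 1 SD each way. Gentamicin and tobramycin at day 1 average 1.02 and 1.05 in the upper panel, where saline rats of that day average -0.16.

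After 5 days of gentamicin, 14 of 14 interferon genes were again higher than in saline (median log2 change 0.59, adjusted p = 1.46e-08, and adjusted p = 0.366 with an estimated correlation). After tobramycin, 13 of 14 were (median 0.74, adjusted p = 4.24e-14, and adjusted p = 0.252 with an estimated correlation). Among 16 measured p53 targets, 15 were higher with gentamicin (median 0.13, adjusted p = 0.000212, and 0.177 with an estimated correlation). Cell cycle genes were higher with both compounds, 22 of 25 each (medians 0.20 and 0.27, adjusted p = 0.000234 and 3.26e-08, and 0.269 and 0.262 with an estimated correlation). Endothelial markers were lower with gentamicin, 0 of 10 being higher (median -0.18, adjusted p = 9.73e-05, and 0.244 with an estimated correlation). Markers of macrophages and granulocytes were called higher with gentamicin, but not with an estimated correlation. That call was kept in 8 of 12 other settings and 4 of 11 fits without a rat. Rats 2F114 and 2M14 had the highest scores for interferon genes (1.42 and 1.27) and for these markers (0.57 and 0.72). Rat 2F115 had the lowest of both (-0.13 and -0.34).

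The largest single change after 5 days of gentamicin was that of Ccl20, a chemokine gene, at 192 ± 114.05 (SD, n = 6) against 35.5 ± 22.5 (SD, n = 5), a log2 change of 2.07 (SE 0.30, 6 of 6 rats, adjusted p = 0.109) that did not pass. Its signal was under 33.2 in 2 of 5 saline rats, so the size depends on the 16 added to each signal. Fitted on the groups compared, 0 genes passed in limma for gentamicin (714 at an unadjusted p under 0.05) and 0 for tobramycin (568). Without saline rat 1F105, 3 passed for gentamicin. In the fit on all arrays Ccl20 rose 3.98-fold (adjusted p = 0.000156) and Atf4, the transcription factor of the integrated stress response, rose 1.64-fold (adjusted p = 0.00189), while tobramycin had 0. For gentamicin, Havcr1 had a log2 change of 0.76, Lcn2 0.0088, Clu 0.52, Cdkn1a 0.52, Hmox1 0.31 and Mt2A 0.013, with adjusted p of 0.459 to 0.993. For tobramycin the values were 0.018, -0.046, 0.45, 0.27, 0.068 and 0.067 in that order, with adjusted p of 0.936 to 0.996.

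Gentamicin and tobramycin share the aminoglycoside scaffold and differ in the groups on their sugar rings. Their dose is not in the labels, so it is unknown whether the doses matched. Tested directly, the compounds differed in 0 genes at day 1 (826 at an unadjusted p under 0.05 in limma) and in 0 at day 5 (663). The interferon list differed by -0.037 log2 at day 1 (95% interval -0.89 to 0.82) and by -0.097 at day 5 (-0.76 to 0.56), and these intervals leave room for a difference either way. For Isg15 at day 1 the difference was 0.0075 (-1.37 to 1.38). Havcr1 was -0.45 (-1.16 to 0.27) at day 1 and 0.69 (-0.10 to 1.48) at day 5. Dbp was 0.72 lower with gentamicin at day 1, written as a difference of -0.72 (-1.12 to -0.32), which did not pass after adjustment (adjusted p = 0.580). Across genes, which are not independent replicates, the changes of both compounds correlated with r = 0.496 at day 1 and 0.659 at day 5. Sharing the same saline rats alone gave r = 0.459 and 0.548 in 20 simulations. With the saline rats split between the compounds, r was 0.110 at day 1 and 0.091 at day 5. Fewer saline rats per compound also add noise, which lowers r. At day 1, leaving out 4M28 gave 1 gene, and at day 5 leaving out 4M33 gave 3.

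Cisplatin is a platinum drug that forms DNA adducts and accumulates in the proximal tubule. After 1 day, 13 of 16 p53 targets were higher than in saline (median 0.11, adjusted p = 0.00279, and 0.215 with an estimated correlation). Ccng1, a p53 target that encodes cyclin G1, had a log2 change of 0.42 (SE 0.14, adjusted p = 0.859) that did not pass. Proximal tubule transporters and enzymes were also higher, 19 of 25 and 19 of 21 genes (medians 0.24 and 0.16, adjusted p = 4.86e-06 and 8.48e-06, and 0.244 and 0.262 with an estimated correlation). The same lists were lower in the saline rats of that day than in naive rats (medians -0.21 and -0.22). Tubular injury markers were lower, with 5 of 22 higher (median -0.10, adjusted p = 0.0119, and 0.332 with an estimated correlation). This call was lost in the fit on all arrays (adjusted p = 0.0653), against naive rats, against saline and naive rats pooled (0.256), without the 5 arrays of absent or differing treatment text, and without 1F103 or 3F120. The calls of transporters and enzymes were lost against naive rats. No gene passed: 0 in limma, with 640 at an unadjusted p under 0.05, and 0 in the fit on all arrays. Havcr1 had a log2 change of 0.20, Lcn2 -0.16, Clu -0.27, Cdkn1a 0.18, Hmox1 -0.97 and Mt2A 0.27, with adjusted p of 0.859 to 0.962.

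After 5 days of cisplatin, p53 targets, tubular injury markers and cell cycle genes were higher. Ccng1 (chromosome 10, 25678503 to 25684876 on GRCr8) rose 2.63-fold, from 621 ± 72.5 (SD, n = 5) to 1673 ± 472 (SD, n = 6), with a log2 change of 1.40 (SE 0.15, adjusted p = 0.00334, higher in 6 of 6 rats). It was the 1 gene that passed when the groups compared were fitted (920 at an unadjusted p under 0.05). Of the p53 list, 15 of 16 were higher with a median of 0.38 (adjusted p = 8.19e-11, and adjusted p = 0.177 with an estimated correlation), and 7 passed adjusted over the list alone. Among 22 injury markers 21 were higher (median 0.43, adjusted p = 1.02e-08, and 0.348 with an estimated correlation). Havcr1 had a signal of 881 ± 1387 (SD, n = 6) against 30.1 ± 11.9 (SD, n = 5), a log2 change of 3.01 (SE 0.89, adjusted p = 0.504) spread from 0.83 to 6.46 over the 6 rats, all higher. The saline signal was under 33.2 in 3 of 5 rats, so the size of this change is uncertain and depends on the 16 added to each signal. Cell cycle genes were higher in 22 of 25 cases (median 0.36, adjusted p = 4.00e-09, and 0.333 with an estimated correlation). The males 3M22 and 3M24 stood apart: their injury scores were 1.03 and 1.595, against 0.077 to 0.40 in the other 4 rats, and their cell cycle scores 0.59 and 0.79, against -0.031 to 0.22. Their p53 scores were 0.63 and 0.95, against 0.25 to 0.50. Adipocyte markers were lower, 0 of 5 being higher (median -0.66, adjusted p = 5.62e-06, and 0.177 with an estimated correlation). Scores of this list also ran from -0.86 to 1.29 among naive rats, and Cfd and Plin1 were each under 33.2 in 3 of 6 cisplatin rats. The size of this fall, and whether it comes from the compound, is therefore uncertain.

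In the fit on all arrays 47 genes changed with cisplatin at day 5 (31 up, 16 down), and examples from it were chosen after their values were seen. Of the p53 list 6 rose, among them Cdkn1a, the cyclin-dependent kinase inhibitor p21 (2.39-fold, adjusted p = 0.00143), Phlda3 (2.22-fold, adjusted p = 0.000257) and Mdm2, the ubiquitin ligase of p53 (1.52-fold, adjusted p = 0.000160). Of the injury list 3 rose: Havcr1 7.43-fold (adjusted p = 0.00725), the fibrinogen chain Fgb 3.47-fold (adjusted p = 0.0262) and Tnfrsf12a 2.38-fold (adjusted p = 0.0104). Immp2l, Wwox and Fhit, which span long stretches of the genome, fell by 1.02, 0.82 and 0.75 on the log2 scale (adjusted p = 4.70e-05, 0.000290 and 0.0104). On the groups compared, Lcn2 had a log2 change of 1.17, Clu 0.91, Cdkn1a 1.29, Hmox1 0.39 and Mt2A 0.20, with adjusted p of 0.391 to 0.671. The count of 1 gene became 3 without 3F122 and 2 without 3M23.

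**Figure D3:**
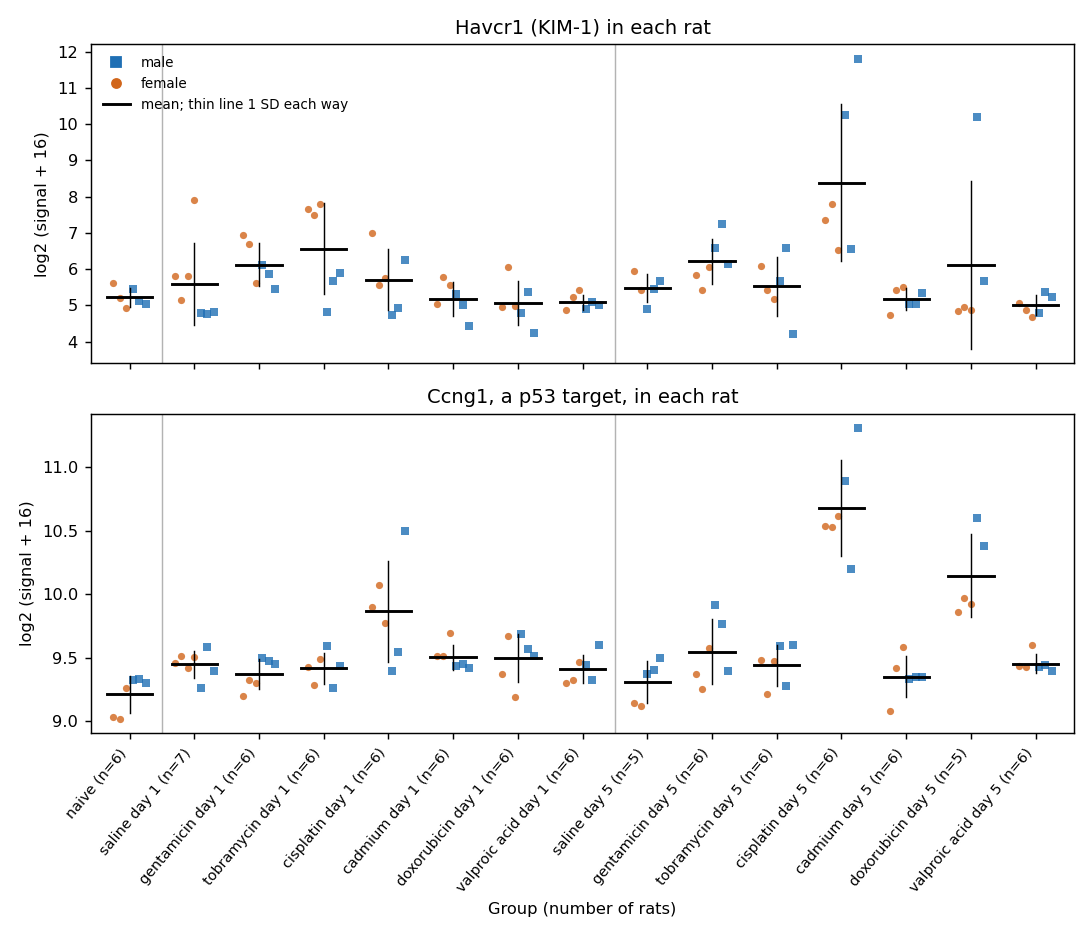
Log2 signal of Havcr1 (upper panel) and Ccng1 (lower panel) in each rat (squares male, circles female), with the group mean as a bar and 1 SD each way as a thin line. The change of Havcr1 spreads from 0.83 to 6.46 among cisplatin rats at day 5, and that of Ccng1 from 0.78 to 1.88.

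Cadmium is a heavy metal that collects in the proximal tubule and induces metallothioneins. After 1 day, the changed genes were those of the circadian clock. Dbp rose 2.72-fold, from 148.2 ± 44.6 (SD, n = 7) to 437 ± 137.8 (SD, n = 6), and the clock repressors Nr1d1 and Nr1d2 rose 1.97-fold and 1.83-fold (adjusted p = 0.0446 each, 6 of 6 rats). Further probe sets of Nr1d2 gave log2 changes of 0.82 and 0.42, where the one used gave 0.87. These were the 3 genes that passed (661 at an unadjusted p under 0.05). The metal response list had a median of -0.025 at day 1 and 0.20 at day 5 and was not called (adjusted p = 0.737 and 0.357, and 0.818 and 0.601 with an estimated correlation). Mt2A had a log2 change of -0.079 at day 1 and 0.25 at day 5 (adjusted p = 0.980 and 1.00). Heat shock genes were lower, with 1 of 12 higher (median -0.22, adjusted p = 1.62e-06, and 0.177 with an estimated correlation). Markers of macrophages and granulocytes were higher in 15 of 15 cases (median 0.19, adjusted p = 3.09e-07, and 0.251 with an estimated correlation). Other log2 changes at day 1 were -0.32 for Havcr1, -0.19 for Lcn2, 0.038 for Clu, -0.14 for Cdkn1a and -0.89 for Hmox1 (adjusted p 0.948 to 0.996). The count of 3 went to 0 without any 1 of 1F101, 1F102, 1F103, 1M2, 1M3, 5F138, 5F139, 5M37 or 5M38. It also went to 0 without the 5 arrays, with the GAPDH ratio as a covariate, all probe sets, array quality weights or the pooled control.

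After 5 days of cadmium, clock genes were higher in 10 of 14 cases (median 0.51, adjusted p = 1.15e-06, and 0.177 with an estimated correlation). Cell cycle genes and proximal tubule transporters were lower, with 4 of 25 and 3 of 25 higher (medians -0.13 and -0.10, adjusted p = 8.84e-05 and 0.00483, and 0.262 and 0.4934 with an estimated correlation). By sex, cell cycle scores were -0.37 to -0.24 in males and -0.015 to 0.049 in females. Transporter scores were -0.79 to -0.27 in females and -0.26, 0.19 and 0.28 in males. A difference between the sexes in these lists was not tested. For single genes, the effect in males minus that in females gave 0 in limma for this group (238 at an unadjusted p under 0.05, where chance gives 571). Collecting duct markers were higher in this group, 12 of 14 (median 0.12, adjusted p = 0.0105, and 0.407 with an estimated correlation), with list scores of -0.79 for transporters and 0.43 for collecting duct in 5F141. Opposite signs of these scores were also seen in every naive rat, so variation between the kidney samples was not separated from the compound. The calls of both were lost without 1F106 or 5M42, that of collecting duct also without 1M6 and that of transporters without 5F141. Both were lost without the 4 arrays of high GAPDH ratio. No single gene passed on the groups compared (0 in limma, 400 at an unadjusted p under 0.05, and 1 without 1F105). In the fit on all arrays 7 did (3 up, 4 down), among them Dbp at 2.65-fold (adjusted p = 0.0162). The GAPDH 3' to 5' ratio, a sign of RNA degradation, was 0.54 ± 0.47 (SD, n = 6) on the log2 scale in this group and 0.65 ± 0.54 (SD, n = 5) in saline. Log2 changes that did not pass were -0.33 for Havcr1, -0.097 for Lcn2, 0.48 for Clu, -0.093 for Cdkn1a and 0.10 for Hmox1 (adjusted p 0.378 to 1.00).

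Doxorubicin is an anthracycline that damages DNA and blocks dividing cells. After 1 day the clock genes Dbp, Nr1d1 and Nr1d2 rose 3.06-fold, 2.30-fold and 1.79-fold (adjusted p = 0.0113, 0.0113 and 0.0105, 6 of 6 rats). Further probe sets of Nr1d2 gave 0.66 and 0.37, against 0.84 for the one used. The clock-controlled repressor Nfil3 fell by 0.90 and the prostaglandin receptor Ptger3 by 0.69 on the log2 scale (adjusted p = 0.0324 and 0.0473). These 5 genes passed, and 1098 had an unadjusted p under 0.05. Red blood cell genes were lower, 1 of 4 being higher (median -0.58, adjusted p = 0.000467, and 0.177 with an estimated correlation). Genes of fatty acid oxidation were lower too, with 4 of 27 higher (median -0.13, adjusted p = 5.14e-07, and 0.177 with an estimated correlation). Collecting duct markers were higher in 14 of 14 cases (median 0.21, adjusted p = 2.42e-05, and 0.353 with an estimated correlation). Proximal tubule transporters had a median of -0.16 and were not called (adjusted p = 0.0975, and 0.622 with an estimated correlation). Scores of transporters and collecting duct also had opposite signs in every naive rat, such as 0.35 and -0.33 in 8M82 and -0.18 and 0.21 in 8M81. Whether the collecting duct rise comes from the compound or from such variation between the kidney samples was not tested. Havcr1 had a log2 change of -0.44, Lcn2 -0.11, Clu 0.12, Cdkn1a 0.34, Hmox1 -0.92 and Mt2A -0.18 (adjusted p 0.492 to 0.908). The count of 5 became 14 without 6F147, 8 without 6F148, 3 without 6M48, 1F101 or 1M1, and 2 without 1F102 or 1M2.

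After 5 days of doxorubicin, red blood cell transcripts were far lower in the kidney than in saline rats. Hbb, the beta chain of hemoglobin (chromosome 1, 167662310 to 167663721 on GRCr8), stood at 68.3 ± 6.43 (SD, n = 5) against 4938 ± 494 (SD, n = 5) in saline, 58.96-fold lower (log2 -5.88, SE 0.10, adjusted p = 4.50e-12). The alpha chain gene Hba-a3 was 10.8-fold lower (33.2 ± 12.8 against 534 ± 125, SD, n = 5 each, adjusted p = 3.04e-06). Alas2, the heme synthesis enzyme of red cell precursors, was at least 4.80-fold lower (9.48 ± 5.07 against 162 ± 34.9, SD, n = 5 each, adjusted p = 3.04e-06). Its signal was under the low-signal limit of 33.2 in all 5 treated rats, so the fold is set against that limit. For Hba-a3, 1 of 5 treated rats was under it, and its fold depends on the 16 added to each signal. All 5 rats showed each fall. Of the 4 red blood cell genes 3 fell, with a median of -3.09 (adjusted p = 5.54e-18, and 0.177 with an estimated correlation).

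Markers of white cells and supporting tissue were also lower in these rats. Of the macrophage and granulocyte genes 2 of 15 were higher (median -0.48, adjusted p = 7.12e-09, and 0.257 with an estimated correlation), of the lymphocyte genes 0 of 7 (median -0.30, adjusted p = 0.000357, and 0.177 with an estimated correlation). Endothelial genes were lower, 0 of 10 being higher (median -0.24, adjusted p = 7.61e-05, and 0.244 with an estimated correlation), and of the fibroblast and matrix genes 3 of 16 were higher (median -0.34, adjusted p = 0.000208, and 0.177 with an estimated correlation). The immunoglobulin gene Ighvl1, the protease inhibitor gene Slpi and the class II gene RT1-Db1 fell by 1.35, 1.40 and 1.05 on the log2 scale (adjusted p = 0.000979, 0.000405 and 0.0251). The signals of Ighvl1 and Slpi were under 33.2 in 5 of 5 treated rats, and against that limit the falls were at least 2.24-fold and 2.66-fold. A further probe set of RT1-Db1 gave -0.18. The p53 target Ccng1 rose 1.90-fold, to 1141 ± 274 (SD, n = 5) from 621 ± 72.5 (SD, n = 5), in 5 of 5 rats (adjusted p = 0.000811). Among 16 p53 targets 13 were higher (median 0.19, adjusted p = 6.77e-05, and 0.177 with an estimated correlation). Trak2, a mitochondrial transport adaptor, rose 1.83-fold (adjusted p = 0.0158), where a further probe set gave a log2 change of 0.12.

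In all, 13 genes passed with doxorubicin at day 5 (2 up, 11 down, 967 at an unadjusted p under 0.05). The count was 6 without 6M49 or 6M50, 7 without 1M4, and 28 without 1F105. In the fit on all arrays 43 did (10 up, 33 down), among them falls of the myeloid genes Csf1r and Ctss by 0.74 and 0.72 on the log2 scale (adjusted p = 0.00466 and 0.0355). Injury markers rested on 1 rat: Havcr1 had a log2 change of 0.89, Lcn2 0.44 and Clu 0.88 on average, against 4.85, 2.71 and 2.89 in 6M49. Cdkn1a had 0.87, Hmox1 0.34 and Mt2A 0.012, and none of these 6 passed (adjusted p 0.330 to 0.982).

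**Figure D4:**
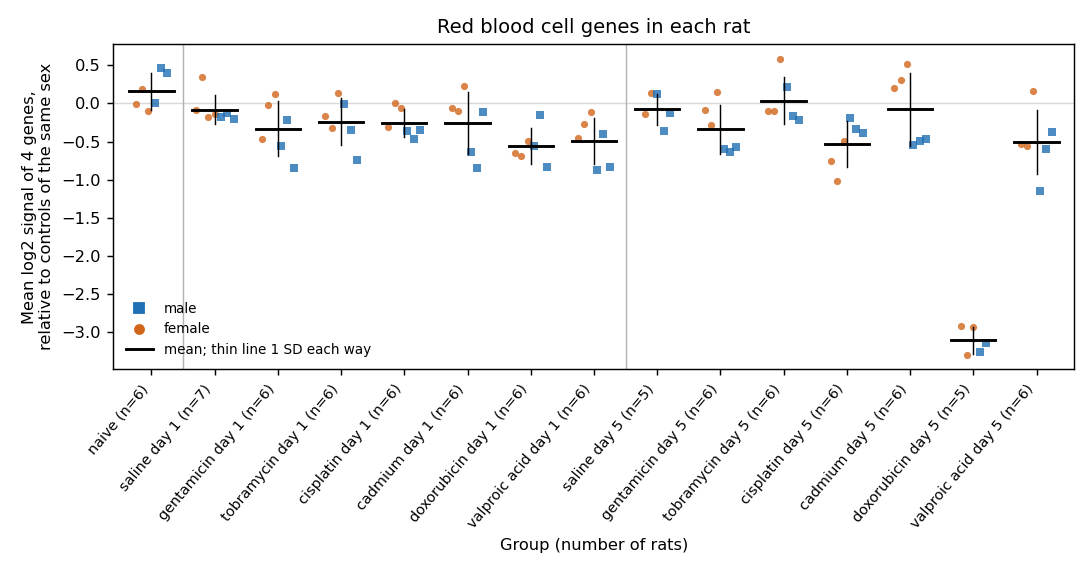
Mean log2 signal of 4 red blood cell genes relative to control rats of the same sex, in each rat (squares male, circles female), with the group mean as a bar and 1 SD each way as a thin line. The 5 doxorubicin rats of day 5 have scores of -3.29 to -2.92, where the saline rats of that day have -0.36 to 0.13.

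Valproic acid is an anticonvulsant that inhibits histone deacetylases. After 1 day, clock genes changed in both directions and cell cycle genes were higher. Dbp rose 3.21-fold, from 148.2 ± 44.6 (SD, n = 7) to 519 ± 141.6 (SD, n = 6, adjusted p = 0.000488), and Per3, Nr1d1 and Nr1d2 rose 2.96-fold, 2.20-fold and 1.83-fold (adjusted p = 0.00295, 0.0129 and 0.00239). The activators Bmal1 and Npas2 fell by 1.19 and 0.92 on the log2 scale (adjusted p = 0.00559 and 0.0211), and Rnf125 and Ptger3 fell by 0.88 and 0.82 (adjusted p = 0.0129 and 0.0211). A further probe set of Per3 gave a log2 change of 0.15, and those of Nr1d2 gave 0.67 and 0.33, against 0.87 for the one used. Cdca3, a regulator of mitotic entry, rose 1.95-fold (adjusted p = 0.0211). Of 25 cell cycle genes 23 were higher (median 0.28, adjusted p = 2.43e-11, and 0.177 with an estimated correlation). The kinase gene Cdk1, the topoisomerase gene Top2a and the proliferation marker Mki67 had log2 changes of 0.80, 0.78 and 0.74 that did not pass (adjusted p = 0.0869 each). The 9 genes named rose or fell in 6 of 6 rats (5 up, 4 down, 1049 at an unadjusted p under 0.05), and the fit on all arrays gave 26. Havcr1 had a log2 change of -0.43, Lcn2 -0.027, Clu 0.19, Cdkn1a -0.068, Hmox1 -0.96 and Mt2A 0.054 (adjusted p 0.763 to 0.985).

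After 5 days of valproic acid, 13 of 14 interferon genes were higher (median 0.55, adjusted p = 4.75e-09, and 0.270 with an estimated correlation). Glucocorticoid response genes were higher in 7 of 7 cases (median 0.47, adjusted p = 0.000212, and 0.305 with an estimated correlation), and adipocyte markers lower, 0 of 5 being higher (median -0.59, adjusted p = 0.000422, and 0.327 with an estimated correlation). Among the adipocyte markers, Plin1 was under 33.2 in 5 of 6 treated rats and Cfd in 3 of 6, and naive rats varied widely in this list, so that fall is uncertain. On the groups compared 0 genes passed in limma (756 at an unadjusted p under 0.05), with 7 without 1F105 and 2 without 1F106. Fitted on all arrays 17 did (4 up, 13 down). In that fit Npas2 fell by 1.48, Rnf125 by 1.08 and the chaperone gene Hsph1 by 0.69 on the log2 scale (adjusted p = 0.000190, 0.000333 and 0.00815), as examples chosen after their values were seen. Havcr1 had a log2 change of -0.48, Lcn2 -0.012, Clu 0.77, Cdkn1a -0.011, Hmox1 0.045 and Mt2A 0.10 (adjusted p 0.352 to 0.996).

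Hmox1, the heme oxygenase gene, had negative log2 changes with all 6 compounds at day 1 (-0.83 to -0.97). The saline rats of that day had a mean of 399 ± 968 (SD, n = 7), a spread larger than the mean itself. Without saline rat 1M1 the changes lay between -0.062 and 0.097, and against naive rats between -0.12 and 0.014, so they rest on that rat.

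Fitted on the groups compared, few changes were shared between nephrotoxicants. At day 1, Dbp, Nr1d1 and Nr1d2 were the 3 genes that passed in the same direction in at least 2 of the 5, and at day 5 Ccng1 was the 1 such gene. No gene passed in 4 of 5 at either day (0 and 0 in limma, from the counts above). In the fit on all arrays 19 genes changed in the same direction with at least 2 of the 5 at day 1, of which 13 rose with both gentamicin and tobramycin. Unchanged groups against the same saline rats gave 0 and 0 on average in 20 simulations. Without an effect almost no gene is called, so these simulations cannot show how much shared saline rats add to an overlap. Independent lists would share 0.0552 rises between the aminoglycosides, but that figure treats genes as independent of each other, which genes of the interferon response need not be. With the 7 saline rats split between these compounds in 35 ways, 0 genes rose with both, and the median number that rose was 0 with gentamicin and 11 with tobramycin. With too few calls for gentamicin the split does not decide, and part of the overlap can come from the shared saline rats. Dbp, Nr1d1, Nr1d2, Rnf125 and Cry1 changed alike with at least 3. In that fit each of them also passed in the same direction with valproic acid at day 1 (log2 1.67, 1.15, 0.87, -0.85 and -0.77 in that order). Their changes are therefore not particular to the nephrotoxicants. At day 5, 7 genes changed alike with at least 2 of the 5 nephrotoxicants and 0 with 3.

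Across the 12 treatment comparisons camera called 107 of 324 list tests with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.177. Lists most often higher were interferon response (10 up, 0 down), circadian clock (9 up, 0 down), immediate early genes and cell cycle (5 up each, 0 and 1 down), p53 targets, collecting duct and inflammatory cytokines and adhesion (4 up, 0 down each). Lists most often lower were heat shock response and red blood cells (0 up, 6 down each), endothelium (0 up, 5 down) and fatty acid oxidation and PPAR targets (0 up, 4 down). Mixed lists were tubular injury markers (3 up, 1 down), macrophages and granulocytes (3 up, 1 down), fibroblasts and extracellular matrix (2 up, 4 down), loop of Henle and distal tubule (1 up, 4 down), adipocytes (1 up, 3 down), ER stress and integrated stress response (2 up, 2 down), lymphocytes (2 up, 1 down), oxidative phosphorylation (1 up, 2 down) and proximal tubule transporters (1 up, 1 down). Nrf2 targets, lysosome, podocytes and glucocorticoid response were up in 2 and down in 0 each, and proximal tubule enzymes up in 1. Metal response and cholesterol biosynthesis were called in 0. Median and mean differed in sign for metal response with gentamicin at day 1 (0.0062 and -0.0071) and tobramycin at day 1 (0.060 and -0.080), and for other lists that were not called.

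Saline and naive rats differ in vehicle and handling, and other differences between these groups were not separated from these. No gene passed: 0 in limma at day 1 (929 at an unadjusted p under 0.05) and 0 at day 5 (675). Tested in the same way as for the treatments, interferon genes were lower in saline rats of day 1, 0 of 14 being higher (median -0.28, adjusted p = 3.15e-10, and 0.332 with an estimated correlation). Proximal tubule transporters and enzymes were lower (6 of 25 and 3 of 21 higher, medians -0.21 and -0.22, adjusted p = 1.80e-06 and 3.19e-06, and 0.360 and 0.332 with an estimated correlation), and so were clock genes (4 of 14 higher, median -0.20, adjusted p = 0.0179, and 0.360 with an estimated correlation). At day 5 transporters were lower as well (4 of 25 higher, median -0.15, adjusted p = 0.000811, and 0.395 with an estimated correlation). Leaving out saline rat 1M1 gave 10 genes at day 1, 1M3 gave 2, and naive rat 8F181 gave 1.

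The effect of a compound at day 5 was compared with its effect at day 1. Doxorubicin had 7 genes that differed (1 up, 6 down, 678 at an unadjusted p under 0.05). Hbb fell by 5.37 more on the log2 scale at day 5 (adjusted p = 1.04e-16), Hba-a3 by 2.66 (adjusted p = 0.000169) and the retinoic acid hydroxylase gene Cyp26b1 by 1.47 (adjusted p = 0.00325), while Ccng1 was 0.84 higher (adjusted p = 0.00957). Alas2 and Ighvl1 also fell more (adjusted p = 0.000154 and 0.000169), without a size because their signal in treated rats of day 5 was under 33.2. For the other compounds 0 genes passed in limma, with 225 at an unadjusted p under 0.05 for gentamicin, 497 for tobramycin, 927 for cisplatin, 299 for cadmium and 599 for valproic acid.

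The mean of the 5 nephrotoxicants was compared with valproic acid of the same day, without saline rats. At day 1, genes that were lower include Top2a by -0.80, Mki67 by -0.73, Cdk1 by -0.66 and Cdca3 by -0.86 on the log2 scale (adjusted p = 0.00142, 0.00556, 0.00142 and 0.00142). Against saline, valproic acid itself had log2 changes of 0.78 for Top2a, 0.80 for Cdk1 and 0.96 for Cdca3, of which that of Cdca3 passed. These differences can therefore come from the valproic acid rats. The metallothionein Mt3 was lower by -0.997 (adjusted p = 0.0428). The lysosomal macrophage gene Cd68 and the cystatin gene Cst7 were 1.51-fold and 1.57-fold higher (adjusted p = 0.0108 each), and Ap2a2, Ptprk and Spcs2 1.24-fold, 1.17-fold and 1.17-fold (adjusted p = 0.0487, 0.0256 and 0.0409). In all 21 genes differed (5 up, 16 down, 1297 at an unadjusted p under 0.05), with 6 without 7F156, 11 without 7M55 and 5 without 7M56. At day 5, Hbb, Mogat2 and Scg5 were lower by -0.89, -0.70 and -0.61 (adjusted p = 0.00402, 0.00402 and 0.00305). These were the 3 genes that passed (699 at an unadjusted p under 0.05), and 5 passed without 7F158. The mean of Hbb includes the doxorubicin rats described above. Mogat2 and Scg5 were higher with valproic acid than with saline at day 5 in the limma fit on all arrays (log2 0.83 and 0.63, adjusted p = 0.0473 and 0.0387).

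Males and females differed in 2699 genes among the 18 control rats (1121 higher and 1578 lower in males, 4140 at an unadjusted p under 0.05), and 242 differed over 2-fold. The organic anion transporter gene Slco1a1 stood at 2316 ± 279 (SD, n = 9) in males and 13.3 ± 4.88 (SD, n = 9) in females, at least 69.4-fold higher (adjusted p = 3.85e-20). Dhrs7l1, Poteml2 and Gc, the vitamin D binding protein gene, were 127-fold, at least 23.1-fold and 22.98-fold higher in males (adjusted p = 1.12e-14, 2.59e-13 and 7.83e-10), beside the Y-linked gene Eif2s3y (at least 19.5-fold, adjusted p = 1.99e-18). Akr1b7, Col24a1, Nxpe2 and Armc3 were at least 36.8-fold, at least 30.3-fold, 17.4-fold and 16.5-fold lower in males (adjusted p = 7.87e-12, 3.10e-15, 1.78e-06 and 1.48e-14), beside Xist (136-fold, adjusted p = 9.85e-14). A fold given as at least was set against the limit of 33.2, because all 9 rats of the lower sex were under it. For the others some were, 6 of 9 for Dhrs7l1 and Gc, 7 for Nxpe2 and Armc3 and 8 for Xist, so these folds depend on the 16 added. Genes of cholesterol biosynthesis and proximal tubule enzymes were higher in males, 14 of 18 and 17 of 21 (medians 0.23 and 0.21, adjusted p = 0.000593 each, and 0.225 each with an estimated correlation). Endothelial markers were lower, 0 of 10 being higher (median -0.25, adjusted p = 0.00816, and 0.225 with an estimated correlation).

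Whether a compound acted differently in males and females was tested in 12 contrasts. Doxorubicin at day 1 gave 3 genes, the glucocorticoid-responsive Sgk1 and Tsc22d3 and the NF-kB inhibitor gene Nfkbia, whose change was 2.15, 1.90 and 1.21 higher in males on the log2 scale (adjusted p = 0.0178 each, 718 at an unadjusted p under 0.05). Gentamicin at day 5 gave 1 gene, Scgb1c1, at 2.78 (adjusted p = 0.0307, 1476 at an unadjusted p under 0.05). In the other contrasts 0 passed in limma, with 238 to 830 at an unadjusted p under 0.05. The total of 4 over all 12 contrasts was 8 without 6F146, 14 without 6M50, 12 without 1F103, 2 without 6F147 or 1F101, and 1 without 6F148, 6M47, 6M48, 1F102 or 1M1. It was 1710 without 1F105, which leaves 1 female in saline at day 5, assumed to vary like the other groups.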

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

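The tests of long genes against RNA quality and against a shift of all day 5 treatments, and the splits of the animals, were chosen before their result was seen. The other tests of the 3 patterns below were chosen only after it, and so were the errors of the shares kept and the interval for the shift.

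Clock genes moved in the same direction with unlike compounds: Dbp rose with tobramycin, cadmium, doxorubicin and valproic acid at day 1. RNA quality is argued against as the whole cause: with the GAPDH ratio as a covariate the log2 change of Dbp had at least 0.967 of its size (SE 0.19). That covariate ended the call of Dbp for tobramycin (1.17, SE 0.18 before and 1.17, SE 0.19 after, adjusted p = 0.0582) and for cadmium (1.44, SE 0.21 before and 1.40, SE 0.22 after, adjusted p = 0.133), where the change moved little and its error grew. Saline rats out of line stay open, since 0.509 to 0.667 of the change was kept against naive rats (SE of the lowest 0.23, from leaving out each rat in turn). The order of the groups at sampling is a candidate explanation that cannot be told apart from the compounds: the mean clock output score (Dbp, Nr1d1, Nr1d2, Per3 and Tef against Bmal1 and Npas2) rose with the group number in the animal codes over 7 groups, with Spearman's rho of 1 at day 1 (exact permutation p = 0.000397, two-sided, adjusted over both days 0.000794) and 0.893 at day 5 (exact p = 0.0123, adjusted 0.0123), Pearson's r of 0.982 and 0.932 (exact p = 0.000397 and 0.00476, adjusted 0.000794 and 0.00476), and r of 0.979 and 0.973 without the 2 groups farthest from the middle number. The genes of the score were chosen after the day 1 calls were seen, so the day 1 values partly restate those calls, while day 5 has other rats of the same compounds. The order of sampling is not in the labels, the naive rats with code 8 scored 0.073, below valproic acid with code 7 (0.89 and 1.06), and group number and compound are confounded. An effect of the compounds on the clock stays open and untested.

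Interferon genes were higher after 1 day of gentamicin and tobramycin, unevenly between rats. The list was also called higher at day 1 with the other 4 compounds (medians 0.16 to 0.46, adjusted p of 0.244 to 0.556 with an estimated correlation) against the same saline rats, in which it was lower than in naive rats, and with none of these 4 was it called higher against naive rats (with cisplatin it was called lower). More macrophages and granulocytes in the tissue are argued against as the whole cause, as far as their markers had signal: the marker medians plus 2 standard errors reached 0.458 at most, below 0.563 and 0.611, which is 0.5 of the interferon medians. S100a9, a member of that list, was under 33.2 in 7 of 7 saline rats, and for such members the bound can be too low. For lymphocyte markers the same bound reached 0.506 at most, but it does not decide, because some of these markers had low signal. Cd3d was under 33.2 in 7 of 7 saline rats and in 6 tobramycin rats. Gzmb was under it in 7 of 7 saline rats and in 4 gentamicin rats. The size of such changes depends on the constant added to each signal, so more lymphocytes stay open. RNA quality, as the GAPDH ratio measures it, is argued against as the whole cause: with that ratio as a covariate the share of the median change kept was 0.994 for tobramycin and 1.22 for gentamicin (SE 0.053 and 0.23 from leaving out each rat in turn), while the genes passing with tobramycin fell to 1. Saline rats out of line may account for part, since 0.692 and 0.698 of the median change was kept against naive rats (SE 0.16 and 0.19). An effect of aminoglycosides stays open, and an infection of some rats was not tested.

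Long genes stood lower after 5 days of cisplatin: 9 of the 16 genes that fell in the fit on all arrays span over 200 kb, against 4.84% of the genes tested. With the 47 called genes left out and each of 543 long genes matched to short genes of like signal, the difference was -0.072 (95% interval -0.13 to -0.0095, two-sided exact permutation p = 0.0260, adjusted over 12 comparisons 0.312), and 3 of 6 rats lay below every saline rat. Without matching it was -0.069, so matching on signal took none of the difference away. As the matched difference did not pass after adjustment, it is itself uncertain, and low signal of long genes stays open. RNA quality is argued against, since the difference was -0.107 (-0.15 to -0.061) with the GAPDH ratio as a covariate. A shift shared by all day 5 treatments is argued against: the largest share of the cisplatin difference in another compound was 0.151, for gentamicin. With the GAPDH ratio as a covariate it was 0.39, also for gentamicin, at -0.042 (-0.075 to -0.0078). The mean of the 5 others lay 0.047 (95% interval 0.016 to 0.077) above the level of 0.5 of the cisplatin difference, and 0.041 (0.017 to 0.066) above it with that covariate. A smaller shift with gentamicin stays open. Blocked transcription of long genes by DNA adducts is a hypothesis that may account for it and was not tested otherwise.

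In each treatment comparison the change of a named gene in single rats was searched for 1 rat far from the rest of its group. This held for 23 of 462 groups, where chance at 1 in 20 gives 23.1. The log2 change of that rat, with that of the nearest other rat in brackets, is given for each. Rat 6M49 of doxorubicin at day 5 had 4.85 (0.33) for Havcr1, 2.71 (-0.19) for Lcn2 and 2.89 (0.41) for Clu. In the same group 6F149 had 0.10 (0.72) for Sert1 and 6F151 had 0.69 (0.34) for Klf4. Rat 3M24 of cisplatin at day 5 had 2.53 (0.95) for Clu and 1.28 (0.64) for Isg15, and 3M23 had -1.37 (-0.87) for Pou3f1. With cisplatin at day 1, 3M21 had 1.07 (0.22) for Cdkn1a and 3F120 had 0.40 (0.16) for Gusb. With gentamicin, 2M10 had 1.00 (0.33) for Clu and 2M12 had 0.015 (0.32) for Bhlhe41 at day 1, and 2F114 had 0.27 (-0.15) for Ech1 at day 5. With tobramycin at day 1, 4F130 had 0.14 (-0.27) for Kcnj1. With cadmium at day 5, 5F140 had -0.97 (-0.32) for Havcr1, 5F142 had -0.68 (-0.33) for Cyp4a3 and -0.21 (0.29) for Scnn1b, and 5F141 had 0.95 (0.37) for Scnn1a. With doxorubicin at day 1, 6F148 had 0.63 (1.64) for Dbp and 6F147 had 0.031 (-0.14) for Ech1. With valproic acid, 7F156 had -0.41 (0.041) for Mt2A and 7F155 had -0.24 (-0.11) for Acadm at day 1, and 7M60 had 0.71 (-1.61) for Cfd at day 5.

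Differences between effects were tested directly. The effect of doxorubicin differed between day 5 and day 1 in 7 genes. Between males and females it differed in 3 genes for doxorubicin at day 1, and for gentamicin at day 5 in 1 gene.

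Each count of genes was set against 40 splits of the same rats into groups of the same sizes, the real split included. Except where the sexes were compared, rats were shuffled without regard to sex, so splits could be less balanced by sex than the real groups. With sex in the model such splits have less power, and their counts may be too low as a measure of chance. For tobramycin at day 1, 1 of 40 splits, the smallest share they allow, gave as many genes. There were 7 genes, at most 1 in another split, but 0 in 10 of 13 fits without a rat. The same share was found for doxorubicin at day 1 (5, at most 0), valproic acid at day 1 (9, at most 1) and doxorubicin at day 5 (13, at most 0). It was also found for nephrotoxicants against valproic acid at day 1 (21, at most 3) and day 5 (3, at most 1), and for males against females (2699, at most 0). Without adjustment over the contrasts, these shares argue against chance. They are too coarse to hold after such an adjustment, so chance is not excluded by these counts. Chance is not argued against by the counts for cadmium at day 1 (3 genes, 2 of 40 splits, at most 5 in another), cisplatin at day 5 (1 gene, 3 of 40, at most 1), doxorubicin at day 5 minus day 1 (7 genes, 2 of 40, at most 10) or doxorubicin at day 1 in males minus females (3 genes, 3 of 40, at most 9). The splits compare only the number of genes and not the strength of a single change. In limma the adjusted p was 0.00334 for Ccng1 with cisplatin at day 5. It was 1.04e-16 for Hbb with doxorubicin at day 5 minus day 1.

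Where 0 genes passed in limma, 40 of 40 splits gave as many. Other splits then gave at most 1 for gentamicin and cisplatin at day 1, for gentamicin and valproic acid at day 5, for saline at day 1 against naive rats and for valproic acid at day 5 minus day 1. They gave at most 7 for tobramycin and 11 for cadmium at day 5, and 3 and 4 for gentamicin against tobramycin at day 1 and day 5. For males minus females at day 1 they gave at most 1 for gentamicin, cisplatin and valproic acid, 2 for tobramycin and 21 for cadmium. Splits reached 198 genes for saline at day 5 against naive rats, and for day 5 minus day 1 they reached 346 with gentamicin, 902 with tobramycin, 20 with cisplatin and over 100 with cadmium, which points to a structure of the samples that was not identified or tested. Males minus females at day 5 had cells of under 3 rats and no splits. The counts at an unadjusted p under 0.05 stand with each comparison above.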

How the results depend on the processing

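The fits without 4 arrays of high GAPDH ratio, with that ratio as a covariate and with a pooled control were chosen after seeing the data; the others were planned. Among the named genes, 11992 comparisons with an alternative stayed on their side of the threshold, 425 lost it, 322 gained it, and 0 turned direction with the threshold passed in either fit. The sign differed in 1.15%, all of them below the threshold in both fits. Where a count below moved, the cause was not tested, except that pooling more arrays in 1 fit adds samples and leaving out arrays removes them. The signal over background limits low genes: those under a signal of 33.2 in all but a few arrays were not tested.

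With the fit on all arrays the counts were 14 for gentamicin, 59 for tobramycin, 6 for cadmium and 26 for valproic acid at day 1, and 2 for gentamicin, 47 for cisplatin, 7 for cadmium, 43 for doxorubicin and 17 for valproic acid at day 5. In that fit they were 1 for cisplatin at day 5 minus day 1, 12 and 7 for nephrotoxicants against valproic acid at day 1 and day 5, and 3 for gentamicin against tobramycin at day 1. Pooling saline and naive rats as control gave 27 for gentamicin, 53 for tobramycin, 0 for cadmium and 33 for valproic acid at day 1, and at day 5 6 for gentamicin, 30 for tobramycin, 44 for cisplatin, 30 for cadmium, 110 for doxorubicin and 86 for valproic acid.

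With naive rats as control there were 1 for gentamicin, 1 for tobramycin, 243 for doxorubicin and 37 for valproic acid at day 1, and 6 for tobramycin, 14 for cisplatin, 15 for cadmium, about 1.3e2 for doxorubicin and 91 for valproic acid at day 5. Array quality weights gave 32 for tobramycin, 0 for cadmium, 3 for doxorubicin and 19 for valproic acid at day 1, 1 for cadmium, 21 for doxorubicin and 5 for valproic acid at day 5, 1 for gentamicin against tobramycin at day 5, and 19 for males minus females. All probe sets gave 0 for tobramycin, 0 for cadmium and 14 for valproic acid at day 1, 2 for cisplatin at day 5, 13 for doxorubicin at day 5 minus day 1, and 5 for nephrotoxicants against valproic acid at day 5.

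Tobramycin at day 1 (7) fell to 0 with a pseudocount of 64, quantile normalization, 1F104 left out or counted at day 5, or without the 5 arrays of absent or differing treatment text, and to 1 with the GAPDH ratio as a covariate. Cadmium at day 1 (3) fell to 0 without those 5 arrays and with the GAPDH ratio. Doxorubicin at day 1 (5) fell to 3 with a pseudocount of 1 or the GAPDH ratio. Cisplatin at day 5 (1) was 2 with a pseudocount of 64, quantile normalization or 1F104 at day 5. Valproic acid at day 5 (0) was 1 with 1F104 at day 5, 2 without the 4 arrays of high GAPDH ratio, and 5 with that ratio as a covariate. Doxorubicin at day 5 (13) was 7 without the 5 arrays. Nephrotoxicants against valproic acid at day 1 (21) was 13 with the GAPDH ratio. Of the 107 lists called, 0 were called with an estimated correlation, and the other alternatives that apply to all arrays or controls kept the number within 1.5 times. Of the 107 calls, 56 were kept in every other setting and 50 also without each rat in turn.

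Leaving out each rat in turn moved the counts over these ranges: gentamicin at day 1 0 to 16, tobramycin 0 to 71, cadmium 0 to 4, doxorubicin 2 to 14; at day 5 gentamicin 0 to 3, cisplatin 1 to 3, cadmium 0 to 1, doxorubicin 6 to 28 and valproic acid 0 to 7. Saline at day 1 against naive rats ran from 0 to 10, nephrotoxicants against valproic acid from 5 to 27 at day 1 and 2 to 5 at day 5, gentamicin against tobramycin from 0 to 1 and 0 to 3, and males minus females from 1 to 1710. The rats behind each move are named with the comparison above. Without 1F105, 1710 rests on the lone saline female 1F106, whose GAPDH ratio was 1.58.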

Other observations

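The paragraphs here report values only, and no test of an explanation was run for them.

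Immediate early genes, the transcription factors induced first after a stimulus, were higher after 5 days of 4 compounds. They were higher in 11 of 12 cases with gentamicin (median log2 change 0.30, camera in limma, adjusted p = 4.82e-05, and 0.225 with an estimated correlation), in 11 of 12 with tobramycin (0.35, adjusted p = 5.62e-06, and 0.177 with an estimated correlation), in 12 of 12 with cisplatin (0.44, adjusted p = 4.86e-06, and 0.357 with an estimated correlation) and in 11 of 12 with doxorubicin (0.16, adjusted p = 0.00950, and 0.4934 with an estimated correlation). The call for doxorubicin was lost in the fit on all arrays (adjusted p = 0.0943), against naive rats, against saline and naive rats pooled (0.312), and without 6F151 or 6M49. Nrf2 targets, the antioxidant response, were higher with cisplatin at day 5 (18 of 21, median 0.18, adjusted p = 0.000212, and 0.257 with an estimated correlation) and with doxorubicin at day 5 (16 of 21, median 0.13, adjusted p = 0.0353, and 0.388 with an estimated correlation). The latter call was kept in 7 of 12 other settings and in 6 of 10 fits without a rat. It was lost in the fit on all arrays (adjusted p = 0.134), with a pooled control (0.373), against naive rats, with array quality weights and with the GAPDH ratio.

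Glucocorticoid response genes were higher after 5 days of cadmium, 7 of 7 (median 0.25, adjusted p = 0.000212, and 0.262 with an estimated correlation). Podocyte markers were higher after 1 day of cadmium (9 of 11, median 0.14, adjusted p = 0.0145, and 0.407 with an estimated correlation) and of doxorubicin (11 of 11, median 0.10, adjusted p = 0.00645, and 0.374 with an estimated correlation), calls lost without 1F103 and without 5F138 or 6F147. Red blood cell genes were lower with cisplatin at day 5, 1 of 4 being higher (median -0.55, adjusted p = 0.00357, and 0.348 with an estimated correlation), and with valproic acid at day 5, 0 of 4 being higher (median -0.53, adjusted p = 0.00279, and 0.356 with an estimated correlation). The call for cisplatin was lost with the GAPDH ratio as a covariate.

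The log2 GAPDH 3' to 5' ratio exceeded 1 in 4 arrays: 1F106 (1.58) of saline at day 5, 5F140 (1.45) of cadmium at day 5, and 7F155 (1.24) and 7F160 (1.04) of valproic acid. The next highest array had 0.81.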
